A study of Homo sapiens with 5 samples.

How the data were processed

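The series holds a pooled genome-wide CRISPR knockout screen in SKM-1, a human leukaemia cell line derived from a myelodysplastic syndrome. In such a screen each cell carries 1 guide RNA that directs Cas9 to cut 1 gene, and the abundance of each guide in the culture is read by sequencing. The 5 libraries are a day 0 culture and cultures at day 7 and day 14, each with decitabine, a hypomethylating nucleoside analogue, or with the solvent DMSO. Each group has 1 library, so no difference between groups has a replicate check. The decitabine dose is not given in the sources used here. The labels call the molecule RNA, although the tables list guides.

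The authors deposited raw read counts per guide in a day 7 table and a day 14 table, with the guide, gene and library named per the file headers. The day 0 column was the same in both tables, with 0 guides differing. The counting tool is not given in the sources used here. The submitters' processing notes list the build mm10, which is a mouse genome, while the guides are named for human genes; no coordinates are printed for this reason. The authors also deposited normalised values, treated here as signal, which were found from the values to be the raw counts multiplied by 1 constant factor per library, separately in the day 7 and the day 14 table. These 2 tables served as an alternative scaling. A further deposited table gave all guides an identical efficiency and was not used here. Guide sequences were not used here.

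The tables hold 119461 guides under 21663 names. Of these guides, 1000 are non-targeting, with a name each. There are 1795 microRNA names and 18868 other gene names, of which 17345 matched a current symbol and 18752 a current or older symbol in a RefSeq gene table that was used for names only. Symbols are printed as the files give them. Guides with a day 0 count of at least 10 were kept, which left 117802 guides (98.6%), and genes with at least 3 such guides were tested, which gave 20334 genes including 1676 microRNA genes. Counts were divided by median-of-ratios size factors.

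For each guide, the log2 ratio of 2 libraries was computed from normalised counts with a pseudocount of 1 and divided by a robust SD of guides of similar abundance, in 50 bins. Guides were ranked, and the ranks of each gene's guides were combined by alpha robust rank aggregation with alpha 0.25, once for lower and once for higher abundance. This guide-set test took its p from 20000000 random guide sets of the same size, so that 5e-08 is the smallest p it can give. Benjamini-Hochberg adjustment was applied per direction and comparison, with a threshold of 0.05. The test compares the libraries, not the conditions, because guides of a gene are not replicate cultures. A gene's value is the median log2 ratio over its guides, followed by the SD over those guides.

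The comparisons were DMSO against day 0 and decitabine against DMSO, each at day 7 and day 14, and the change of the decitabine effect between the days, which makes 5 tested comparisons. Decitabine against day 0 was computed as values without a test. The groups, tests, 18 gene lists, named genes and other settings were fixed before the data were examined. Named genes were, per comparison and direction, the 10 genes with the lowest p past the threshold, or the 5 with the lowest p where fewer than 5 passed, together with members of each list with the lowest p and with OGDH, DLST, DLD, DCK, SLC29A1, CDA, SAMHD1, DCTD and DNMT1. A list's median was placed among 10000 random lists of the same size matched on day 0 abundance, as a description of these libraries. Backgrounds were 166 sets of 6 non-targeting guides and 369 olfactory receptor genes.

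The other settings were total-count scaling, scaling on non-targeting guides, the authors' normalised values, no day 0 filter, a day 0 count of at least 50, a pseudocount of 5, the mean standardised log2 ratio as gene statistic with fewer random sets, and the residual of decitabine against day 0 after regression on DMSO against day 0. After the data had been seen, 3 more were added: libraries thinned to the lowest total of 13871459, the mean of both days, and edgeR's quasi-likelihood test per guide with day as a block, which has 1 residual degree of freedom.

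The guide-set test was tested on simulated data, with counts drawn from the real means and spreads and 200 genes changed in all of their guides. For day 14 decitabine against DMSO, 20.0% of genes with a simulated log2 change of -1 and 90.0% of those with -2 were called, and 34.0% and 98.0% of those with 1 and 2, with 4 of 20134 unchanged genes called. For day 7 decitabine against DMSO, these were 50.0% and 100.0%, 58.0% and 100.0%, and 0 genes. For day 14 DMSO against day 0, they were 28.0% and 100.0%, 36.0% and 100.0%, and 8 genes. Real guides differ in cutting, so these shares are upper estimates. Total counts ran from 13871459 to 25607693 per library, and a count of 0 allowed a share of up to 3 counts of the total, from 0.117 to 0.216 CPM. Intervals are at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.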

Results

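Guide abundance was measured in 5 libraries of SKM-1 cells carrying a genome-wide knockout library, to find genes whose loss alters growth of the culture or its response to decitabine. The day 0 library held 20459274 counts. The day 7 libraries held 13871459 counts with DMSO and 20713491 with decitabine, and the day 14 libraries 17431877 and 25607693. Of 119461 guides, 233 were at a count of 0 at day 0 (0.195%, 95% Wilson interval 0.172 to 0.222). With DMSO, 602 guides were at 0 at day 7 (0.504%, 0.465 to 0.546) and 921 at day 14 (0.771%, 0.723 to 0.822). With decitabine, 331 guides were at 0 at day 7 (0.277%, 0.249 to 0.309) and 635 at day 14 (0.532%, 0.492 to 0.574). The Gini index, a measure of unevenness, was 0.381 at day 0, 0.399 and 0.389 at day 7, and 0.418 and 0.410 at day 14, with DMSO and decitabine respectively. The most abundant 1% of guides took between 4.44% and 4.72% of the counts in each library. At each day the decitabine library held more counts than the DMSO library. Guides at 0 and the Gini index were not compared at equal depth, so they do not show less guide loss with decitabine. Each group had 1 library, so values below carry the SD over guides and no replicate error.

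Between day 0 and day 14 in DMSO, the genes whose guides fell included members of the ribosome list (6 of 78), the DNA replication list (1 of 45) and the mitotic spindle and cohesin list (1 of 41). RPL3, a protein of the large ribosomal subunit, fell by 2.96 ± 1.14 on the log2 scale (SD over 6 guides), and RPS28 of the small subunit fell by 2.38 ± 0.82 (5 guides). GAPDH, a glycolytic enzyme, fell by 2.38 ± 1.33, WDR74, a ribosome assembly factor, by 2.07 ± 2.47, RRM2, a subunit of ribonucleotide reductase, by 2.03 ± 1.14, and PELO, a ribosome rescue factor, by 1.99 ± 1.04. The transcription factor MYC fell by 1.67 ± 1.99. In all, 40 of 20334 genes fell by the guide-set test at an adjusted p under 0.05 and 0 rose, where the lowest adjusted p for higher abundance was 0.745. At an unadjusted p under 0.05, 1253 genes were lower and 1088 higher, against 1017 that chance gives per direction. Genes picked by a low p in 1 DMSO library can have overstated falls. At day 14, RPL3 (1.47 ± 0.91), RPS28 (1.47 ± 0.61) and RRM2 (1.19 ± 0.84) were higher with decitabine than with DMSO, without passing the guide-set test. These genes were among the members of their lists with the lowest p for higher abundance with decitabine by that test. They therefore do not measure how far falls were overstated. The other genes named here are not compared in this way.

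The remaining genes among the 10 with the lowest p at day 14 belong to families with near-identical copies. WASH1, a subunit of an endosomal actin-nucleating complex, fell by 2.99 ± 1.64. The microRNA hsa-mir-6859-1 fell by 2.92 ± 1.28 and SPDYE2, of the Speedy cell cycle regulator family, by 1.51 ± 0.98, each over 4 guides. GAGE1, a cancer-testis antigen, fell by 1.28 ± 0.84 and the olfactory receptor OR4F17 by 1.34 ± 0.98. Guides of these genes, and of the other genes named above, were not checked for matches to other copies. No gene passed for higher abundance; the 5 with the lowest p were WIPI1 (0.81 ± 0.69), FBXO21 (0.76 ± 0.26), ENGASE (0.90 ± 0.34), GLI3 (1.05 ± 0.91) and HIATL1 (0.32 ± 1.14).

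At day 7 in DMSO, 22 genes fell against day 0 and 0 rose by the guide-set test, with 1121 lower and 1085 higher at an unadjusted p under 0.05. RPL3 fell by 1.98 ± 1.17, CAD, which starts pyrimidine synthesis, by 1.60 ± 0.82, and RNPS1, a splicing-dependent RNA-binding protein, by 1.47 ± 2.83. WASH1 fell by 1.45 ± 0.85, SMN1, which assembles splicing particles, by 1.36 ± 1.24, SPDYE2 by 1.21 ± 0.81, FOXD4L2 by 1.02 ± 0.66, the histone gene HIST2H2AA3 by 0.93 ± 2.22, GOLGA6L1 by 0.70 ± 0.79 and hsa-mir-1233-1 by 0.68 ± 0.86. SMN1, FOXD4L2, HIST2H2AA3, GOLGA6L1 and hsa-mir-1233-1 also have close copies. None passed for higher abundance, where TIMP2 (0.76 ± 0.46), hsa-mir-6766 (0.86 ± 2.08), STX1A (-0.06 ± 1.41), RGS1 (0.64 ± 0.41) and TMEM86A (0.26 ± 0.79) had the lowest p. With a day 0 count of at least 50, 7 genes fell at day 7. Of the 22 genes, 12 also fell at day 14, where independent lists would share 0.0433 and the highest overlap in 20 simulations of unchanged groups against the same day 0 library was 0. Those simulations called at most 0 genes at day 7 and 1 at day 14, so their overlap could not exceed 0. Independent lists leave out the shared library, and part of the excess may come from the shared day 0 library. Among the 12 genes, SPDYE2, WASH1, GAGE1, SMN1, GOLGA6L1, AGAP4, hsa-mir-1233-1 and hsa-mir-6859-1 have close copies. The others were RPL3, RPL10, SPC24 and BUD31, whose guides were not checked for other matches. The overlap therefore does not separate a need for these genes from an effect of copies.

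The lists of core cellular machinery were lower in DMSO at both days. The 78 cytosolic ribosome genes had a median of -0.52 at day 7 and -0.69 at day 14; 3 and 6 of them fell over all genes tested, and 38 and 45 adjusted over the list alone. The proteasome list (32 genes) had medians of -0.40 and -0.46, with 0 called over all genes at either day and 12 and 13 adjusted over the list alone, among them PSMB3 (-1.41 ± 1.49) and PSMA6 (-1.29 ± 1.93) at day 14. PSMA2 had the lowest p of that list at day 14 with a median of 0.41 ± 2.0, so its median and its test differ in sign. The core spliceosome list (44 genes) had medians of -0.33 and -0.65, with BUD31 called at each day (-1.78 ± 0.68 and -1.23 ± 2.68) and 12 and 18 members adjusted over the list alone. The mitotic spindle and cohesin list (41 genes) had medians of -0.36 and -0.65; SPC24, a kinetochore protein, fell at day 7 (-1.25 ± 1.09) and at day 14 (-1.76 ± 0.97), and 7 and 11 members passed adjusted over the list alone. The RNA polymerase list (25 genes) had medians of -0.18 and -0.44, with POLR3K called at day 14 (-1.67 ± 1.03) and 2 and 4 members adjusted over the list alone. The DNA replication list (45 genes) had medians of -0.19 and -0.46, with RRM2 called at day 14 and 6 and 5 members adjusted over the list alone. The medians of these 6 lists at day 14 lay at percentile 0.0 among the random lists, and at day 7 between 0.0 and 1.25.

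Metabolic and regulatory lists had day 14 medians between -0.22 and 0.07, several of them below most random lists. The TCA cycle and pyruvate dehydrogenase list (34 genes) had medians of -0.08 at day 7 and 0.00 at day 14 with 0 members called by the guide-set test over all genes or adjusted over the list alone. In this list, OGDH, the first subunit of the 2-oxoglutarate dehydrogenase complex, had values of -0.29 ± 0.71 and 0.04 ± 0.80, its partner DLST -0.23 ± 0.84 and -0.22 ± 0.71, and DLD -0.37 ± 0.76 and -0.60 ± 0.71; none passed, with an unadjusted p of 0.0262 and 0.0293 for lower abundance of DLD and of 0.0302 for higher abundance of OGDH at day 14. The glutamine and glutamate metabolism list (38 genes) had medians of -0.10 and 0.07, with CAD called at day 7, MYC at day 14, and 3 and 4 members lower adjusted over the list alone. The oxidative phosphorylation list (65 genes) had medians of -0.04 and -0.16 with 0 called over all genes or over the list alone, and a percentile of 0.28 at day 14. The glycolysis and pentose phosphate list (29 genes) had medians of -0.18 and -0.19 (percentiles 0.74 and 1.31), with GAPDH called at day 14; adjusted over the list alone, 1 member was higher at day 7 and 2 were lower at day 14, GAPDH and TPI1 (-1.20 ± 1.60). The myeloid transcription and signalling list (56 genes) had medians of -0.16 and -0.13 (percentiles 0.10 and 1.30), with MYC called at day 14 and with MYC and CCND3 (-0.62 ± 0.88) among the members lower at day 7 adjusted over the list alone. The decitabine uptake and metabolism list (29 genes) had medians of -0.13 and -0.22 (percentiles 3.20 and 0.60), with DUT (-1.40 ± 1.05) and DHODH (-1.60 ± 1.26) lower at day 14 adjusted over the list alone. The DNA damage response and repair list (80 genes) had medians of -0.04 and -0.10 (percentiles 23.9 and 2.31), with RAD9A (-2.43 ± 1.98), XRCC6 (-1.88 ± 1.5) and HUS1 (-1.72 ± 1.47) lower at day 14 adjusted over the list alone. The DNA methylation list (27 genes; -0.04 and 0.05), the apoptosis list (37 genes; -0.07 and -0.04) and the growth restraining list (48 genes; -0.03 and -0.04) had 0 members called by the guide-set test in either direction, over all genes or adjusted over the list alone.

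Of the controls, 0 of 166 non-targeting sets passed in DMSO at either day, while 30 at day 7 and 37 at day 14 had an unadjusted p under 0.05 for higher abundance and 0 for lower. At the p of the called genes, hardly any of 166 sets would pass by chance. Non-targeting guides were also shifted to higher abundance, with medians of 0.13 and 0.24. These sets therefore do not measure false calls of lower abundance. The 369 olfactory receptor genes had medians of 0.00 and 0.07 (percentiles 94.3 and 100), with 0 called at day 7 and OR4F17 at day 14. The 1676 microRNA genes had medians of -0.03 and -0.03 (percentiles 0.06 and 0.85), with 2 called at day 7 and 3 at day 14. Scaling on the non-targeting guides moved the median of all genes by -0.13 at day 7 and by -0.25 at day 14. With that scaling all 18 lists had medians below 0, the olfactory receptors at -0.12 and -0.19 and the ribosome list at -0.65 and -0.95; this shift is common to all genes, so the sign of a median near 0 depends on the scaling.

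**Figure D1:**
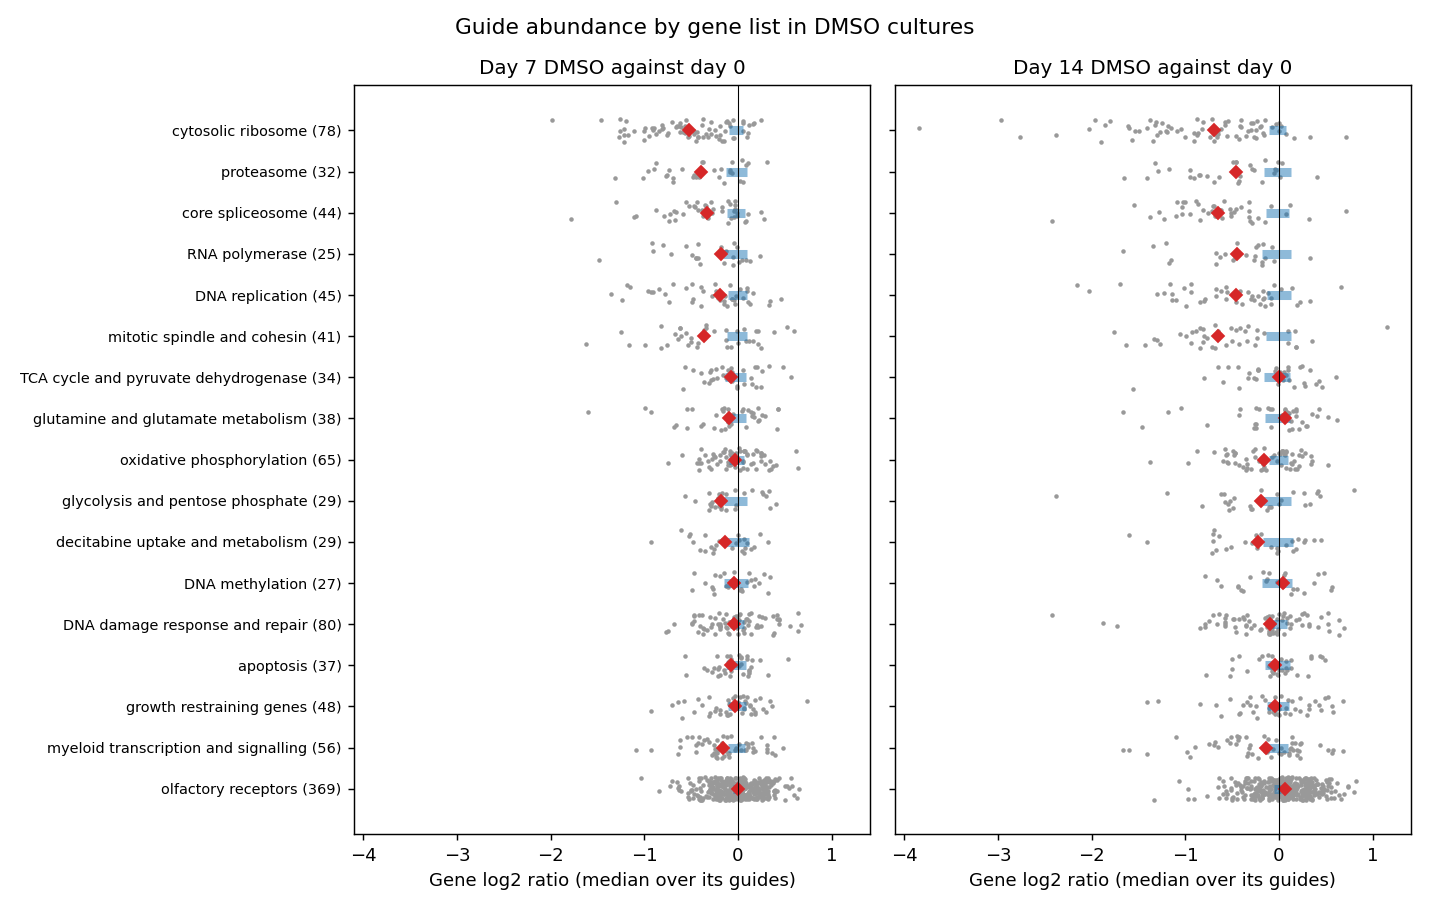
Gene values by list in DMSO at day 7 and day 14, as log2 ratio to day 0. Grey points are genes (median over guides), red diamonds list medians, and blue bars the central 95% of medians of 10000 matched random lists; the ribosome median lies at -0.52 and -0.69, left of its bar, and the olfactory receptor median at 0.00 and 0.07.

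Between decitabine and DMSO, no gene passed at either day. At day 7 the guide-set test called 0 genes lower and 0 higher, with 1024 and 1026 at an unadjusted p under 0.05, where chance gives 1017, and lowest adjusted p of 0.189 and 0.448. At day 14 it called 0 and 0, with 1061 and 1036 at an unadjusted p under 0.05 and lowest adjusted p of 0.904 and 0.665. The mean standardised log2 ratio also called 0 genes in either direction, with 970 lower and 960 higher at an unadjusted p under 0.05 at day 7 and 1049 and 1078 at day 14. edgeR's quasi-likelihood test per guide over both days, chosen after seeing the data, called 151 guides lower and 119 higher. Of 117802 guides, 12303 were at an unadjusted p under 0.05 by this test, a larger share than the 0.05 that chance gives. Non-targeting guides had a Pearson r of 0.261 between the decitabine effects at day 7 and day 14. The edgeR test takes the days as independent replicates, so its p may be too small. It called 0.200% of non-targeting guides (2 of 1000; exact 95% interval 0.0242 to 0.721) and 0.229% of targeting guides (268 of 116802; 0.203 to 0.259), and hsa-mir-7974 was the 1 gene with at least 2 guides called in the same direction.

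The genes with the lowest p at day 7, none past the threshold, were the receptor tyrosine kinase EPHB1 (-0.62 ± 0.11), LRRC47 (-0.86 ± 0.86), UNC13B (-0.87 ± 0.95), hsa-mir-6766 (-0.11 ± 1.62) and DCAF4 (-1.51 ± 1.04) for lower abundance. For higher abundance they were WDR41 (0.75 ± 0.87), hsa-mir-3131 (1.39 ± 1.62), UCP3 (0.66 ± 0.23), the ribosomal protein gene RPS20 (0.91 ± 0.17) and PRRT1 (0.14 ± 0.96). At day 14 they were ZCCHC10 (-1.70 ± 1.14), the decoy receptor gene IL1R2 (-0.56 ± 1.23), HIATL1 (-0.35 ± 1.97), TMEM235 (-1.29 ± 0.71) and hsa-mir-7974 (-1.52 ± 1.71) for lower abundance. For higher abundance at day 14 they were RGS9 (1.83 ± 1.12), TBX4 (0.46 ± 1.15), LRRTM2 (0.07 ± 1.09), C1RL (0.69 ± 0.26) and ITGB1BP2 (0.68 ± 0.99). HIATL1 and hsa-mir-6766 were also among the lowest p for higher abundance in DMSO against day 0, which uses the same DMSO library. Their low p can come from an outlying guide, since edgeR called a guide of each lower (log2 -2.30 and -2.78). It also called guides of UNC13B, DCAF4 and hsa-mir-7974 lower and of WDR41 and PRRT1 higher. The edgeR test used these same libraries, so a called guide is not shown to be an outlier. Because the DMSO library is shared, the low p of HIATL1 and hsa-mir-6766 in both comparisons is not separate evidence.

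OGDH, which the series title names in connection with resistance to hypomethylating agents, had guides of lower abundance with decitabine than with DMSO without passing the test. Its value was -1.26 ± 1.26 at day 7, with 6 of 6 guides below 0, an unadjusted p for lower abundance of 0.0173 and an adjusted p of 0.972 by the guide-set test, which ranked it 349 of 20334. At day 14 it was -0.88 ± 1.63, with 5 of 6 guides below 0, p of 0.0742, adjusted p of 0.982 and rank 1529. The day 0 counts of its guides ran from 12 to 240 with a median of 63.5, against 145.0 over all guides. With a day 0 count of at least 50, OGDH kept 3 guides and its values were -0.33 at day 7 and -0.55 at day 14. If the study chose OGDH on these samples, which the sources used here do not state, its values are not independent evidence of its direction.

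Genes that handle decitabine did not pass either. DCK, the kinase that activates decitabine, had values of 0.16 ± 0.40 at day 7 and 0.23 ± 1.5 at day 14, and the nucleoside transporter gene SLC29A1 0.27 ± 0.48 and 0.25 ± 0.58. CDA and DCTD, which encode deaminases, had 0.12 ± 0.45 and -0.41 ± 0.50 at day 7 and 0.17 ± 1.54 and 0.17 ± 0.81 at day 14. SAMHD1, a triphosphohydrolase, had -0.51 ± 0.48 and -0.18 ± 0.52, and DNMT1, the maintenance DNA methyltransferase, 0.36 ± 0.64 and 0.49 ± 0.68. DLST had 0.07 ± 0.50 and 0.04 ± 0.60 and DLD -0.18 ± 0.99 and 0.04 ± 2.22. Adjusted p for these 8 genes was at least 0.984 in either direction at both days.

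**Figure D2:**
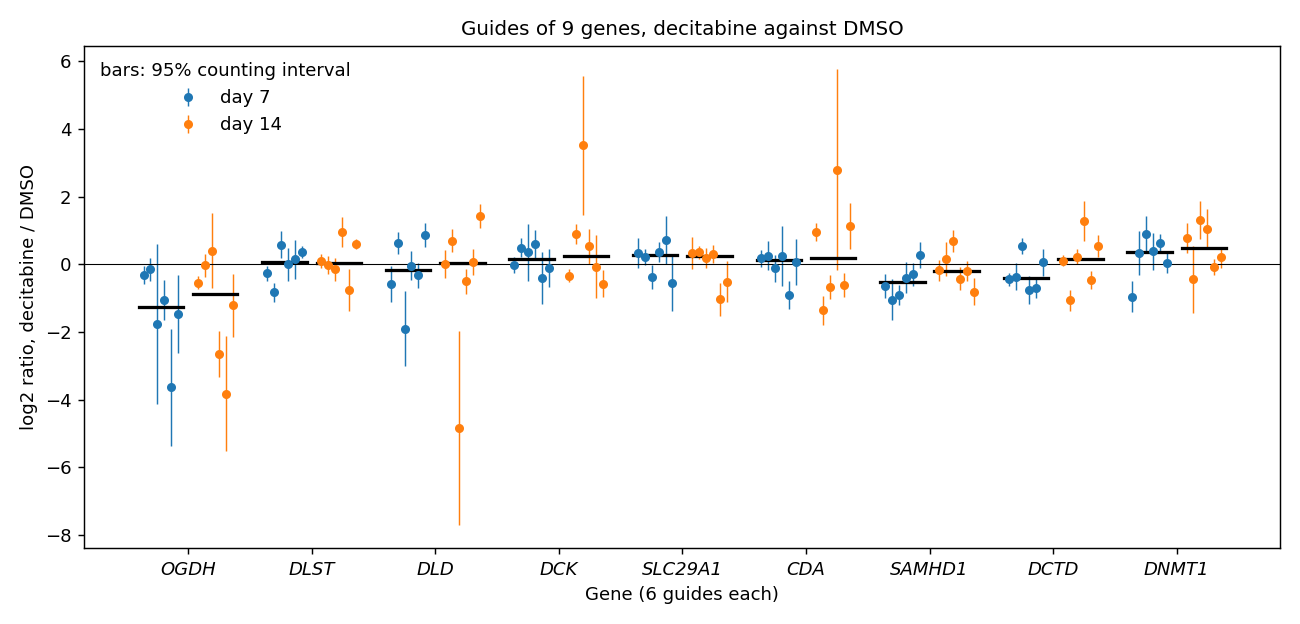
Log2 ratio of decitabine to DMSO for the 6 guides of each of 9 genes, with day 7 in blue and day 14 in orange. Vertical bars are 95% counting intervals and black lines medians; OGDH medians lie at -1.26 and -0.88 and those of DCK at 0.16 and 0.23.

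No list member passed over all genes between decitabine and DMSO. The decitabine uptake and metabolism list had medians of 0.13 at day 7 and 0.17 at day 14, at percentiles 98.3 and 98.6 among random lists, with 0 members called over the list alone; with a day 0 count of at least 50 the medians were 0.05 and 0.04. The DNA methylation list had medians of 0.04 and 0.11. At day 7, MORC2 (0.65 ± 0.78), HELLS (0.68 ± 0.28) and MBD2 (0.72 ± 0.37) were higher adjusted over the list alone. Their adjusted p by the guide-set test was 0.0335 each in the list and 0.828, 0.885 and 0.885 over all genes. At day 14, 0 members of the DNA methylation list passed over the list alone. In the ribosome list (medians 0.00 and 0.00), RPS20 was higher at day 7 adjusted over the list alone, and in the glycolysis list (-0.02 and -0.02) 1 member was higher at day 14. Glutamine and glutamate metabolism had medians of 0.00 and -0.11, the latter at percentile 4.50, and the TCA cycle list 0.06 and 0.00. The other lists had medians between -0.07 and 0.10 at both days with 0 members passing over the list alone. With 18 lists and 2 days, some percentiles this far out can arise by chance, but how many was not tested. The decitabine uptake and metabolism list was low in DMSO against day 0 (percentiles 3.20 and 0.60). That comparison uses the same DMSO libraries, and low DMSO values raise the ratio of decitabine to DMSO.

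The change of the decitabine effect from day 7 to day 14 was largest by p for C1RL, a complement-related protease (0.95 ± 0.54, adjusted p 0.0722), and did not pass. The guide-set test called 0 genes lower and 0 higher, with 1033 and 1058 at an unadjusted p under 0.05. Of the lists, glutamine and glutamate metabolism had 1 member lower and DNA methylation 1 member higher adjusted over the list alone, and 0 over all genes. The next genes for higher values were ADAMTSL5 (1.25 ± 0.71), SCN10A (-0.04 ± 1.33), HIST2H2BF (0.05 ± 2.10) and PRX (1.18 ± 0.90), and for lower values CHD8 (-0.87 ± 1.11), EMP3 (-1.32 ± 0.37), ACAD10 (-1.14 ± 0.53), HIATL1 (-0.61 ± 1.78) and DDX26B (-0.98 ± 1.94). Without the day 0 filter, C1RL passed, and with the mean statistic C1RL and ADAMTSL5 passed, where 985 genes were lower and 1041 higher at an unadjusted p under 0.05. The change for OGDH was -0.03 ± 1.21. Across genes, which are not independent replicates, the day 7 and day 14 effects had a Pearson r of 0.158 and a Spearman rho of 0.148.

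**Figure D3:**
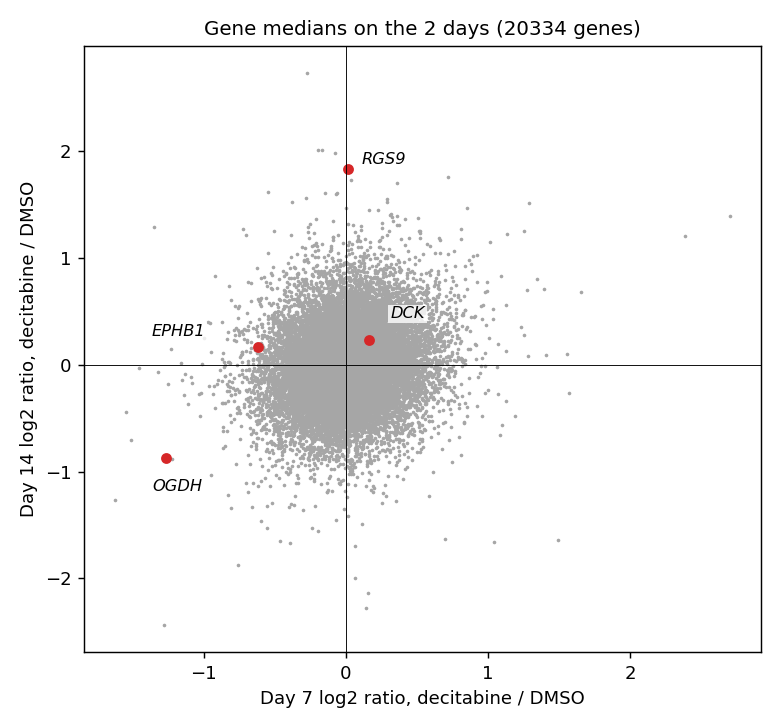
Gene log2 ratio of decitabine to DMSO at day 7 (horizontal) and day 14 (vertical), each point a gene and its value the median over guides. Across 20334 genes r was 0.158; the named points are OGDH at -1.26 and -0.88, RGS9 at 1.83 on day 14, EPHB1 at -0.62 on day 7 and DCK at 0.16 and 0.23.

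Set against day 0, the core machinery lists were also lower in the decitabine cultures; these are values with no test, and they share the day 0 library. The ribosome list had medians of -0.52 at day 7 and -0.72 at day 14, the core spliceosome list -0.38 and -0.65, the proteasome list -0.41 and -0.51, and the RNA polymerase list -0.39 and -0.52. The DNA replication list had -0.21 and -0.32 and the mitotic spindle and cohesin list -0.23 and -0.29. Oxidative phosphorylation had -0.08 and -0.30.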

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

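The thinning, the mean of both days, edgeR per guide and the share of counting error over all guides were chosen after seeing the data. In DMSO against day 0, the 22 genes lower at day 7 became 7 with a day 0 count of at least 50 (6 of them shared) and 34 with the mean standardised log2 ratio (18 shared), and the 40 at day 14 became 91 with the mean statistic (38 shared). Under the other alternatives the counts were 21 to 26 at day 7 and 35 to 50 at day 14, and 0 genes were higher under each. The causes were not tested. Between decitabine and DMSO the counts stayed at 0 under each alternative except the residual after regression on DMSO against day 0, which gave 3 lower at day 7 (ATP6AP1, DCAF4 and hsa-mir-6859-1) and 1 lower at day 14 (SPDYE2). The regression slopes were 0.418 and 0.395, so residuals can keep part of a loss that both arms share. SPDYE2 had -0.15 between the arms and -1.51 in DMSO against day 0, and hsa-mir-6859-1 -0.73 and -1.38, but ATP6AP1 had -0.83 and -0.37 and DCAF4 -1.51 and 0.43, so shared loss does not account for DCAF4. The change of the decitabine effect gave 1 gene higher without the day 0 filter and 2 with the mean statistic, and 0 with total-count scaling, a day 0 count of at least 50 or a pseudocount of 5; non-targeting scaling, the authors' values and thinning were not run on it, and the cause was not tested. Over named genes, 841 values under alternatives kept their side of the threshold or their value within the SD over guides, 7 moved, 4 newly passed, 6 no longer passed and none reversed. Of list medians, 374 were within their error of the value reported and 58 moved; 36 of these are all lists in DMSO against day 0 under non-targeting scaling, which shifts every gene alike and so says nothing of single lists. The alternatives on sub-libraries of guides were not run, because guide names give no sub-library. No paired analysis was possible within a day because each group has 1 library; edgeR with day as a block paired the arms across days, with 1 residual degree of freedom. Counting error made up 14.5% of the variance of the log2 ratio over targeting guides at day 7 and 8.77% at day 14.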

Other observations

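The tests of shared drift over non-targeting guides, of abundance-matched guide sets, of non-targeting against olfactory receptor guides and of the ZNF genes were chosen after the results were seen. The duplicated families were picked after the called genes had been seen and before their own values were.

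Non-targeting guides ended higher than guides against olfactory receptors in DMSO. Their median log2 ratio to day 0 was 0.13 against 0.02 at day 7 and 0.24 against 0.07 at day 14, a difference of 0.18 at day 14 (95% bootstrap interval over guides 0.13 to 0.21). Among guides with day 0 counts from 150 to 500, the day 14 difference was 0.22 (0.17 to 0.27). Between decitabine and DMSO at day 14 it was 0.01 (-0.03 to 0.06). The 491 ZNF zinc finger genes had a median of 0.04 between decitabine and DMSO at day 7, at percentile 99.7, and of 0.02 at day 14, at percentile 81.6.

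Several genes lower in DMSO belong to families of near-identical copies, among them WASH1, SPDYE2, GAGE1 and GOLGA6L1. A candidate explanation is that guides cut several copies at once, and cutting itself slows growth. Other duplicated families, 85 genes such as NBPF, POTE and SSX members, had a day 14 median of -0.07 at percentile 17.83 among random lists, short of the 2.5 set beforehand; 6 of them were lower adjusted over the list alone. That bound alone would have counted against the explanation, but the list left out the called genes and mixes families of unlike similarity, so the explanation and a growth role of these genes cannot be told apart here. Guide sequences, which would decide it, were not used here.

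No gene passed between decitabine and DMSO. For abundant guides, sequencing depth is argued against as the cause. Counting error made up 6.565% of the variance at day 14 over 888 non-targeting guides with at least 100 counts in both libraries. Their log2 ratio had an SD 3.903 times that of counting error, over the 1.5 set beforehand. With 1 library per arm, random loss of cells, unequal amplification and drift cannot be told apart. The filter on counts keeps counting error low, so these values do not cover guides with low counts. Over all targeting guides the share was 8.77% at day 14. Pooled over all genes, guides of a gene shared no detectable response. The intraclass correlation was 0.0034 at day 14, within the -0.0064 to 0.0045 of 100 shuffles, while day 14 DMSO against day 0 gave 0.0534. A pooled value cannot exclude a response limited to a few genes. A weak or absent effect of the unstated dose stays open as untested.

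OGDH was low with decitabine at both days. Chance among all genes stays open by the rule set beforehand. At both days 3 genes were as low (OGDH, hsa-mir-1299 and hsa-mir-301a), within the 0 to 3 of 100 shuffles. However, 1 shuffle alone reached 3 and the median was 0. OGDH itself set the bound, so it is counted by construction, while the shuffles had no such member. Of 100000 guide sets matched to the abundance of OGDH, 0.00200% were as low at both days. Over the genes tested this would be 0.407 genes if all had its abundance. That share rests on very few of the sets and has no interval, so it is imprecise. OGDH was looked at because the series title names it. Whether it was picked on these samples is not stated in the sources used here. Drift shared by both days of an arm may contribute, since non-targeting guides had r of 0.261 between the days, with a 95% range of 0.112 to 0.289 in equal-sized sets of targeting guides. A biological effect of OGDH loss stays open as well, and replicate cultures would be needed to separate these.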
